A study of Mus musculus with 18 samples.

How the data were processed

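Bulk RNA was sequenced from MC38-OVA tumours, a mouse colon carcinoma line made to express the model antigen ovalbumin, grown in wild-type (WT) mice or in mice lacking Adra2a (KO). Hosts received clonidine, guanabenz or PBS daily by intraperitoneal injection, and tumours were collected 7 days after treatment, per the labels, which give an age of 10 weeks and no doses. The 18 libraries form 6 groups of 3, taken from the sample titles. The 3 libraries titled KO-Guanabenz carry the treatment entry untreated, so their treatment is in conflict between labels; the title was followed and the conflict is stated wherever they are used. Nothing in the labels says which animals the libraries came from, so p-values measure the spread between these libraries, which may be technical in part.

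The deposited table holds estimated counts per gene, which the authors made by trimming with Trim Galore 0.6.5 and quantification with kallisto 0.46.0 against GRCm38, per the submitters' processing notes. The values are whole numbers as deposited, and how transcript estimates were summed to genes is not given in the sources used here. Library strandedness is likewise not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart. kallisto divides reads that match several transcripts between them, so values for near-identical families are uncertain; among the genes named in the report these are the ribosomal proteins, the globins, Esp8, H2ac11 and the Gbp, Klra, Serpina3, Pira, H2 and Scd genes.

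The table has 21015 gene identifiers, of which 20994 matched a symbol in the RefSeq annotation of GRCm38.p6. The 21 others held at most 0.022% of the counts in any library, and 1829 genes had no counts. Totals per library ran in units of 1e6 from 54.7 to 491.1 with a median of 92.4. At these totals counting error is small for most tested genes; the precision was set by the spread between libraries, with a biological coefficient of variation of 0.145.

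Genes were kept with filterByExpr, which left 16125. Libraries were scaled by TMM and all 18 were fitted with 6 group means in edgeR 4.0.16 (R 4.3.3), so that the groups share 1 estimate of the spread (12 residual and 4.35 prior degrees of freedom). Two-sided quasi-likelihood tests were adjusted by the Benjamini-Hochberg method within each comparison, and adjusted p under 0.05 counted as a call. Fold changes are given on the log2 scale with standard errors (SE), and levels as counts per 1e6 counts (CPM) with the SD between libraries. The 9 comparisons were each treatment against control within a genotype, KO against WT under control and under clonidine treatment, clonidine against guanabenz in WT mice, and the difference of each drug's effect between genotypes. A further comparison, KO against WT averaged over the 3 treatments, was added after the data were seen.

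Before the data were examined, the groups, tests, 40 gene lists, alternative settings and the rule for named genes were fixed. The lists cover immune cell types, stromal and other tissue cells, cytokine and antigen presentation programmes, cell cycle, stress and metabolic programmes, and adrenergic signalling; 39 could be tested and 1 had no member in the table. Some genes belong to more than 1 list, so results of such lists are not independent. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 between genes, and adjusted over the 39 lists. Each test was repeated with the correlation estimated from the data and with fry. For list members a second adjustment was made over the list alone. The rule for named genes took 30 key genes in comparisons of 2 groups, up to 8 higher and 8 lower called genes with the largest change, a mean log2 CPM of at least 1 and no overlap between groups, up to 4 members with the smallest p from each called list, and, where fewer than 5 genes passed, the 5 with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

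Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and total-count scaling, no low-count filter, a stricter filter, the replicate number as a block, a fit of the compared groups alone, omission of each library, omission of the KO-Guanabenz libraries, and those libraries read as KO-Control. A term for Y-linked transcripts and a list test after removal of each library's trend with transcript length (lengths found for 98.5% of genes) were added after the data were seen, as were 1000 random gene sets matched to a list in transcript length and mean level, given as the central 95% of their medians. For the clonidine difference, the share due to Y-linked status was bounded by the 95% limit of its effect on a list's mean level, fitted beside group, times the imbalance of 0.33 between the groups; differences of mean list level are between group means of log2 CPM. These were also taken for every called list without each library, after the data were seen. Counts were simulated for 16125 genes, each gene independently of the others. The changed genes whose recovery was counted were drawn from those with a mean log2 CPM of at least 1, so the shares do not cover scarcer genes. The test of WT clonidine against WT control recovered 76.1% of genes changed 1.5-fold, 91% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls. For the difference of the clonidine effect between genotypes the shares were 46.3%, 86.6% and 98.5%, with 9 false calls. With no gene changed, 0 genes were called in 3 simulated comparisons.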

Results

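RNA was measured in tumours from 6 groups of 3 libraries: WT-Control, WT-Clonidine, WT-Guanabenz, KO-Control, KO-Clonidine and KO-Guanabenz. MC38-OVA cells carry their own genome, so only host cells in the tumour lack Adra2a in the KO groups. Clonidine and guanabenz are both agonists of alpha2-adrenergic receptors, the class to which the Adra2a product belongs. Total counts, in units of 1e6, ranged from 54.7 in WT-Guanabenz 1 to 491.1 in WT-Control 3, with 275.1 in WT-Clonidine 2. Transcripts of 3 Y-linked genes (Ddx3y, Eif2s3y and Uty) averaged above 1 CPM in 11 libraries: 3 of 3 in WT-Control, 2 of 3 in WT-Clonidine, WT-Guanabenz, KO-Control and KO-Guanabenz, and 0 of 3 in KO-Clonidine. The labels do not give the sex of the mice.

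Adra2a (gene 11551, chromosome 19, 54045259 to 54048982, GRCm38), the disrupted gene, was scarce in every library. It lay between 0.286 and 0.589 CPM in the 9 WT libraries and between 0.0917 and 0.293 CPM in the 9 KO libraries, so the ranges overlapped slightly. In KO-Control it was at 0.179 ± 0.0647 CPM against 0.425 ± 0.153 in WT-Control (SD, n = 3), a log2 difference of -1.2 (SE 0.34, adjusted p = 1 in edgeR over all genes). Over all treatments the difference was -1.22 (SE 0.2, adjusted p = 0.016). Residual reads in KO tumours ranged from 7 to 37 counts per library. The tumour cells, which carry their own genome, are a possible source. Which part of the gene was disrupted is not given in the sources used here. The libraries titled KO-Guanabenz, whose treatment entry reads untreated, held 0.0917, 0.139 and 0.171 CPM.

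The effect of clonidine in mice with the receptor was read from WT-Clonidine against WT-Control. T cell genes were higher: all 20 tested members of the T cell list had positive changes, with a median of 0.76 (1.69-fold, quartiles 0.54 and 0.85), and 16 passed when adjusted over the list alone, against 0 over all genes (camera adjusted p = 1.9e-11, adjusted p = 0.42 with an estimated correlation). Cd6 and Cd5, surface receptors that tune T cell receptor signalling, were higher by 1.16 (SE 0.28) and 0.95 (SE 0.24). Cd3e, a chain of the receptor complex, went from 3.16 ± 1.05 to 5.74 ± 1.08 CPM (SD, n = 3). Ribosomal protein genes were lower in all 25 members (median -0.18), 20 of them when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.6e-15, adjusted p = 0.42 with an estimated correlation). Among them were Rps14 (-0.44, SE 0.1) and Rpl13 (-0.29, SE 0.06). Gene sets matched to the list in transcript length and level had medians from -0.17 to -0.06. Genes of hypoxia and glycolysis were also lower, with 21 of 22 below 0, a median of -0.59 and 10 passing when adjusted over the list alone against 0 over all genes (camera adjusted p = 7.5e-11, adjusted p = 0.49 with an estimated correlation). Members include Ldha, which makes lactate (-0.5, SE 0.13), Pdk1, which inhibits pyruvate dehydrogenase (-0.77, SE 0.2), and Ddit4, an inhibitor of mTORC1 (-0.68, SE 0.14).

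Other immune lists were called higher as well, while the naive and memory lymphocyte list and the B cell and plasma cell list were not called. In the checkpoint and exhaustion list (median 0.32, camera adjusted p = 3.2e-05, adjusted p = 0.42 with an estimated correlation), Tox, a transcription factor of chronically stimulated T cells, was higher by 1.24 (SE 0.31), and the inhibitory receptors Tigit and Pdcd1 by 0.75 (SE 0.22) and 0.69 (SE 0.21). Of its 15 members 4 passed when adjusted over the list alone and 0 over all genes. In the regulatory T cell list (median 0.38, adjusted p = 0.00067, adjusted p = 0.42 with an estimated correlation), Foxp3, the factor that defines these cells, went from 1.88 ± 0.165 to 3.33 ± 0.321 CPM. Ikzf4, a partner of Foxp3, and the cytokine gene Il10 differed by 0.81 (SE 0.22) and 1.09 (SE 0.37), and 3 of 10 members passed when adjusted over the list alone and 0 over all genes. Mast cell and eosinophil genes had the highest list median, 1.38 (adjusted p = 3.4e-05, adjusted p = 0.49 with an estimated correlation), with Cpa3, a mast cell protease, at 1.97 (SE 0.6) and Ccr3, an eosinophil chemokine receptor, at 0.94 (SE 0.3). When adjusted over the list alone 7 of 12 passed, with 0 over all genes, and levels were low, Cpa3 reaching 3.63 ± 1.65 CPM. Interferon gamma response genes had a median of 0.23 (adjusted p = 0.00016, adjusted p = 0.6 with an estimated correlation). The GTPases Iigp1 (0.56, SE 0.14), Gbp7 (0.46, SE 0.13) and Gbp8 (0.98, SE 0.3) were the 3 of 30 that passed when adjusted over the list alone, with 0 over all genes.

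Other lists called higher were NK cell (median 0.4), alternative macrophage (0.37), lymphocyte-attracting chemokines (0.33), conventional dendritic cell (0.25), endothelial cell (0.23) and pericyte and smooth muscle (0.23), in none of which a member passed either adjustment (adjusted p from 0.49 to 0.67 with an estimated correlation). The integrated stress response list was lower (median -0.23, adjusted p = 6e-04, adjusted p = 0.49 with an estimated correlation), with 8 members lower and 2 higher when adjusted over the list alone and 0 over all genes. Trib3, a pseudokinase, and Asns, which makes asparagine, both targets of the transcription factor ATF4, differed by -1.01 (SE 0.18) and -0.47 (SE 0.11), and Sesn2, a leucine sensor, by -0.51 (SE 0.1). Oxidative phosphorylation genes had a median of -0.09 (adjusted p = 0.00016, adjusted p = 0.49 with an estimated correlation), with Cox4i1, Ndufb8 and Ndufa1 passing when adjusted over the list alone and 0 over all genes, and sets matched to this list in transcript length and level had medians from -0.13 to -0.03. The 8 erythroid genes had a median of -0.88 (adjusted p = 0.042, adjusted p = 0.68 with an estimated correlation). Markers that did not pass include the cytotoxic effector list (median 0.2, adjusted p = 0.27), in which Gzmb was -0.19 (SE 0.35) and Prf1 0.16 (SE 0.28), and the macrophage and monocyte list (0.03, adjusted p = 0.66).

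At the level of single genes edgeR called 0, with 2079 genes at an unadjusted p under 0.05 where chance gives 806 and a smallest adjusted p of 0.066. DESeq2 called 355 and voom 773. Genes with the smallest p were Tlr1, a receptor for bacterial lipopeptides (0.61, SE 0.1), Mzt2 (-0.44, SE 0.08), Rtcb, a tRNA ligase (-0.31, SE 0.05), Trib3 and Pafah1b3 (-0.54, SE 0.1), each at adjusted p = 0.066. In all, 16 lists passed camera, 11 higher and 5 lower. None of these 16 held with an estimated correlation, and fry called 0. Without 1 library the difference of mean levels fell by over 1.5 times in 2 of the 16 (NK cell, 0.44 to 0.29 without WT-Control 1, and endothelial, 0.16 to 0.11 without WT-Control 3). Omission of WT-Control 2 gave 55 called genes.

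**Figure D1:**
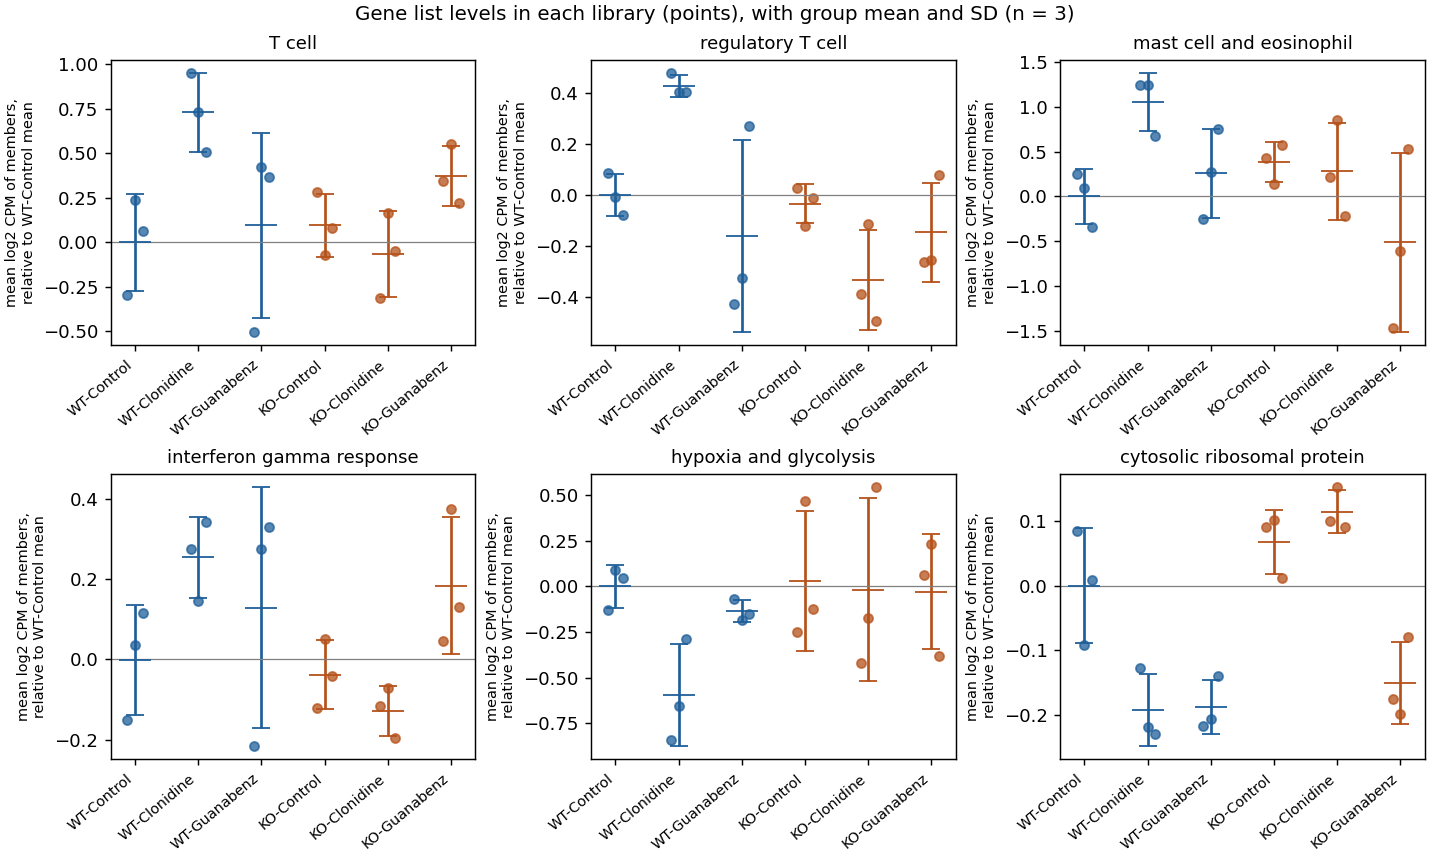
Level of 6 gene lists in each of the 18 libraries (points), as mean log2 CPM of the members relative to the WT-Control mean, with group mean and SD (n = 3; WT blue, KO orange; the libraries titled KO-Guanabenz carry a treatment entry of untreated). The T cell list stands at 0.51 to 0.95 in WT-Clonidine and between -0.3 and 0.23 in WT-Control, and the ribosomal list is below 0 in all libraries of WT-Clonidine, WT-Guanabenz and KO-Guanabenz.

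Clonidine in mice without the receptor was read from KO-Clonidine against KO-Control. Apol8, an apolipoprotein L family member, fell by 1.46 (SE 0.19), from 55.7 ± 4.7 to 20.3 ± 5.51 CPM, Rab11fip1, a Rab11 effector of endosome recycling, fell by 0.97 (SE 0.14), and Esp8, a secreted peptide gene of a multicopy family, fell by 2.97 (SE 0.42) to 0.366 ± 0.194 CPM (adjusted p = 0.015 for each). The T cell list had a median of -0.17 (adjusted p = 0.14), with Cd3e at -0.15 (SE 0.31) and Cd8a at 0.07 (SE 0.36). Erythroid genes had a median of 1.76 with all 8 positive (adjusted p = 0.99 with an estimated correlation). Hba-a1, an alpha globin, was at 685 ± 523 CPM against 208 ± 103. Fibroblast and matrix genes had a median of 0.18, with Col1a1, a chain of type I collagen, at 0.52 (SE 0.17). Skeletal muscle genes had a median of -0.44, with Mb, the oxygen carrier of muscle, at -1.03 (SE 0.43). KO-Clonidine 3 carries much of these lists, since without it the differences of mean levels went from 1.3 to 0.75 (erythroid), 0.17 to 0.03 (fibroblast and matrix) and -0.53 to -0.17 (skeletal muscle).

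In this comparison edgeR called those 3 genes, all lower, with 890 at an unadjusted p under 0.05, against 29 by DESeq2 and 3 by voom. The other lists of the 5 that passed were the integrated stress response (0.08, with Sdf2l1, a chaperone partner, at 0.46, SE 0.13) and ribosomal protein (0.04), whose differences of mean levels went from 0.09 to 0.01 without KO-Clonidine 3 and from 0.05 to 0.02 without KO-Control 3. In none of the 5 did a member pass over all genes or when adjusted over the list alone. Each of the 5 had adjusted p = 0.99 with an estimated correlation. Omission of KO-Clonidine 1, KO-Clonidine 2 or KO-Control 2 left 1 call, and omission of KO-Clonidine 3 or KO-Control 1 left 0. With the KO-Guanabenz libraries, whose treatment label is in conflict, read as KO-Control, 0 genes were called, as with the replicate number as a block or with these groups fitted alone. Y-linked transcripts were present in 0 of 3 KO-Clonidine and 2 of 3 KO-Control libraries, and a term for them left 1 call.

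The difference between those effects asks whether the response to clonidine depends on the receptor. T cell genes responded more in WT than in KO mice: all 20 were positive, with a median difference of 0.79 (camera adjusted p = 1.6e-10, adjusted p = 0.36 with an estimated correlation). Cd6 (1.93, SE 0.4), Cd5 (1.61, SE 0.34), Icos (1.32, SE 0.42), a costimulatory receptor, and Themis (1.48, SE 0.49) were the 4 that passed when adjusted over the list alone, against 0 over all genes. The checkpoint list (adjusted p = 0.36 with an estimated correlation) had a median of 0.48, with 5 of 15 passing when adjusted over the list alone and 0 over all genes, among them Ctla4 (1.46, SE 0.48), Tox (1.39, SE 0.44) and Tigit (1, SE 0.31). In the regulatory T cell list (0.64, adjusted p = 0.36 with an estimated correlation) Foxp3 (1.35, SE 0.41) and Ikzf4 (1.18, SE 0.32) passed in the same way, with 0 over all genes. In the opposite direction, all 25 ribosomal protein genes were below 0 (median -0.23, adjusted p = 0.36 with an estimated correlation), 15 of them when adjusted over the list alone and 0 over all genes. The integrated stress response list was at -0.3 (adjusted p = 0.36 with an estimated correlation), with 7 of 25 passing when adjusted over the list alone and 0 over all genes. Trib3 was at -1.01 (SE 0.25) and Chac1, which degrades glutathione, at -0.85 (SE 0.25). All 22 hypoxia genes were negative (median -0.58, adjusted p = 0.57 with an estimated correlation), Ddit4 (-0.87, SE 0.2) being the 1 that passed when adjusted over the list alone, against 0 over all genes. The 8 erythroid genes had a median of -2.65 (adjusted p = 0.5 with an estimated correlation), with 5 passing when adjusted over the list alone and 0 over all genes.

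Of the 17 lists called in this difference, 11 were higher in the WT response. Beside those above they were mast cell and eosinophil (1.26, with Ccr3 at 1.68, SE 0.44, passing when adjusted over the list alone and 0 over all genes), alternative macrophage (0.59), NK cell (0.58), lymphocyte-attracting chemokines (0.51), skeletal muscle (0.47), conventional dendritic cell (0.31), interferon gamma response (0.3) and endothelial cell (0.26). On the lower side were fibroblast and matrix (-0.23) and oxidative phosphorylation (-0.13). edgeR called 0 genes, with 1442 at an unadjusted p under 0.05 and a smallest adjusted p of 0.057, against 37 by DESeq2 and 2 by voom. Sh3gl3 (-1.45, SE 0.22), an endophilin, Apol8 (1.73, SE 0.27) and Esp8 (3.56, SE 0.57) had the smallest p. They were followed by Map3k10 (-0.39, SE 0.07) and Kcnt2 (2.57, SE 0.52) at adjusted p = 0.3. All 17 list calls were lost with an estimated correlation, with adjusted p from 0.36 to 0.6. Without KO-Clonidine 3 the differences of mean levels fell by over 1.5 times in 3 of the 17: hypoxia from -0.55 to -0.27, skeletal muscle from 0.72 to 0.36 and fibroblast and matrix from -0.17 to -0.03. All 3 KO-Clonidine libraries lacked Y-linked transcripts, and with a term for these 2 genes were called.

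Guanabenz in WT mice was read from WT-Guanabenz against WT-Control. Ribosomal protein genes were again lower in all 25 members, with a median of -0.18 (camera adjusted p = 2.1e-15, adjusted p = 0.87 with an estimated correlation) and 19 passing when adjusted over the list alone against 0 over all genes. Rps14 was at -0.46 (SE 0.1) and Rps3 at -0.29 (SE 0.07). Changes followed transcript length, with medians of -0.08 in the shortest 20% of genes and 0.1 in the longest 20%, and sets matched to the ribosomal list in length and level had medians from -0.19 to -0.08. Oxidative phosphorylation genes had a median of -0.13 (adjusted p = 0.98 with an estimated correlation). Cox4i1 (-0.26, SE 0.06), a subunit of cytochrome oxidase, and Ndufb8 (-0.34, SE 0.09), one of complex I, passed when adjusted over the list alone, with 0 over all genes, and sets matched to this list had medians from -0.14 to -0.06. Cell cycle genes were slightly higher, at 0.08 for the G2 and M phase list and 0.1 for S phase (adjusted p = 0.99 for both with an estimated correlation). The proliferation marker Mki67 went from 284 ± 11 to 343 ± 18.2 CPM and, with the centromere proteins Cenpf and Cenpe, passed when adjusted over the list alone (adjusted p = 0.038), with 0 over all genes. The T cell list had a median of 0.17 with 13 of 20 positive (adjusted p = 0.57), and Foxp3 was at 0.14 (SE 0.29).

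edgeR called 0 genes, with 1845 at an unadjusted p under 0.05, against 171 by DESeq2 and 6 by voom. The smallest p belonged to Per2, a repressor of the circadian clock, at 10.9 ± 0.772 against 4.96 ± 1.3 CPM (log2 1.15, SE 0.17, adjusted p = 0.05 when rounded). Next were Mastl, a mitotic kinase (0.38, SE 0.07), Ctdspl2 (0.37, SE 0.07), Sft2d1 (-0.26, SE 0.05) and Marchf1 (0.44, SE 0.09), each at adjusted p = 0.14. The remaining list of the 5 called was the integrated stress response (-0.12). Its adjusted p was 0.99 with an estimated correlation, where 0 of the 5 held. Differences of mean levels fell by over 1.5 times in 2 of the 5 lists, S phase (0.1 to 0.07 without WT-Guanabenz 1) and the integrated stress response (-0.12 to -0.06 without WT-Control 3). The 5 list calls became 14 without WT-Guanabenz 1, 9 without WT-Guanabenz 2, 8 without WT-Control 3 and 3 without WT-Control 2. Without WT-Control 1 the gene count was 1.

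**Figure D2:**
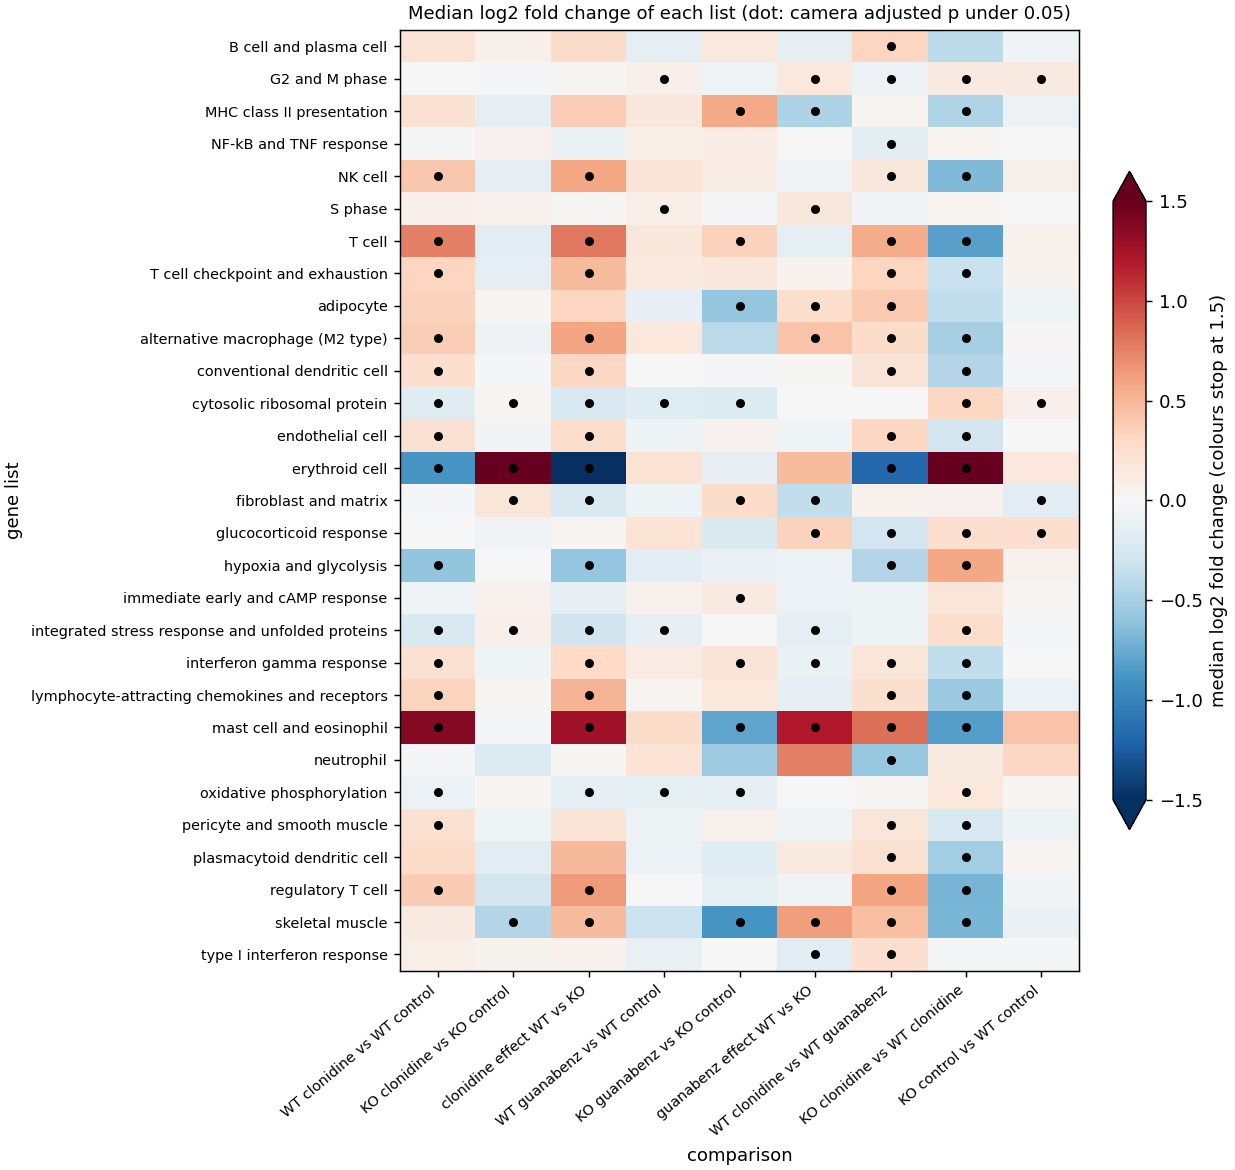
Median log2 fold change of each gene list that passed camera in at least 1 of the 9 planned comparisons (rows) in each comparison (columns), with a dot where the adjusted camera p was under 0.05. The colour scale stops at 1.5 on either side, and none of the marked calls held with an estimated correlation.

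Clonidine and guanabenz both carry a dichlorophenyl ring, joined to an imidazoline ring in clonidine and through a hydrazone link to an open guanidine in guanabenz. Their doses are not given in the labels, so a difference can reflect dose. T cell genes were higher with clonidine: all 20 were positive (median 0.56, camera adjusted p = 2.3e-14, adjusted p = 0.29 with an estimated correlation). WT-Guanabenz 1 stood apart, with a T cell level of -0.5 relative to WT-Control against 0.42 and 0.36 in WT-Guanabenz 2 and 3, and without it the difference of mean levels went from 0.63 to 0.34. Cd5, at 1.03 (95% interval 0.52 to 1.54), was the 1 that passed when adjusted over the list alone and 0 over all genes. The regulatory T cell list had a median of 0.59 (adjusted p = 0.18 with an estimated correlation), with the transcription factor genes Ikzf4 (0.9, interval 0.43 to 1.37) and Ikzf2 (0.52, SE 0.16) passing when adjusted over the list alone and 0 over all genes. Vessel genes were also higher, with Plvap, a protein of endothelial fenestrae, at 0.43 (interval 0.21 to 0.66), 1 of 3 in the endothelial list (median 0.31, adjusted p = 0.35 with an estimated correlation) that passed when adjusted over the list alone, with 0 over all genes. Rgs5 of pericytes, at 0.41 (interval 0.16 to 0.65), was the 1 in its list (median 0.18, adjusted p = 0.35 with an estimated correlation), again with 0 over all genes. Among the libraries of these groups both vessel lists were lowest in WT-Guanabenz 1. Without it the differences of mean levels went from 0.27 to 0.12 (endothelial) and from 0.17 to 0.08 (pericyte). Hypoxia genes were lower with clonidine in all 22 members (median -0.44, adjusted p = 0.35 with an estimated correlation), and Pdk1 was at -0.65 (interval -1.08 to -0.22), with 0 passing either adjustment. Ribosomal protein genes did not separate the compounds, with a median of 0 (quartiles -0.02 and 0.02, adjusted p = 0.72).

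The remaining higher lists were mast cell and eosinophil (0.83), skeletal muscle (0.45), adipocyte (0.39), B cell and plasma cell (0.32), checkpoint (0.32), alternative macrophage (0.27), type I interferon (0.25), lymphocyte-attracting chemokines (0.24), plasmacytoid dendritic cell (0.23), conventional dendritic cell (0.19), interferon gamma (0.18) and NK cell (0.17). The last 2 turned direction without WT-Guanabenz 1 (differences of mean levels -0.05 and -0.04, adjusted p = 0.3 and 0.52). Without it the differences also went from 0.39 to 0.07 (lymphocyte-attracting chemokines), 0.34 to 0.15 (plasmacytoid dendritic cell), 0.37 to 0.21 (conventional dendritic cell), 0.28 to 0.16 (checkpoint) and 0.49 to 0.29 (B cell and plasma cell), and for type I interferon from 0.24 to 0.07 without WT-Clonidine 1. The remaining lower lists were erythroid (-1.18), neutrophil (-0.57), glucocorticoid response (-0.29), NF-kB and TNF response (-0.16) and G2 and M phase (-0.09). The difference of mean levels went from -0.73 to -0.01 for erythroid genes without WT-Guanabenz 1 and from -0.1 to -0.02 for G2 and M phase without WT-Clonidine 3. The neutrophil gene Retnlg (-3.65, SE 1.04) passed when adjusted over the list alone, with 0 over all genes, and the cytokine gene Il6 was at -3.12 (SE 0.93, 5.18 ± 7.62 CPM in WT-Guanabenz). WT-Guanabenz 3 stood apart, with levels relative to WT-Control of 1.19 for neutrophil, 1.16 for NF-kB and TNF response, 1.58 for myeloid-attracting chemokines and 2.09 for skin epidermis genes. Without it the differences of mean levels went from -0.72 to -0.27 (neutrophil) and from -0.46 to -0.03 (NF-kB and TNF response), and in camera the list NF-kB and TNF response, WT clonidine vs WT guanabenz, without WT-Guanabenz replicate 3 turned direction (adjusted p = 0.36). No single gene separated the compounds in edgeR, which called 0 with 814 at an unadjusted p under 0.05, close to the 806 that chance gives, against 4 by DESeq2 and 1 by voom. H2ac11, a histone gene, had the smallest p (-1.33, interval -1.83 to -0.83, adjusted p = 0.55), followed by Hey1 (0.67, SE 0.14), a Notch target, Usp28 (-0.25, SE 0.05), Gm21188 (0.58, SE 0.13) and Ltf (1.85, SE 0.43). Intervals stayed wide for low genes, from -0.29 to 1.24 for Cd8a and -1.01 to 0.48 for Gzmb, and narrow for C1qa of macrophages (-0.11 to 0.29), so the results do not show that the compounds act alike. Differences of mean levels thus fell by over 1.5 times without 1 library in 15 of the 22 called lists. Of the 22 list calls none held with an estimated correlation, where the adjusted p ranged from 0.18 to 0.61. Omission of WT-Guanabenz 3 gave 1 called gene.

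Across all genes the changes with clonidine and guanabenz in WT mice had a correlation of 0.53, with 73.5% of genes sharing a sign. Both use the same controls: for groups with no effect, 1000 simulated draws gave a mean correlation of 0.49 (0.13 to 0.78) and 66.9% of shared signs. The covariance was 0.0426 against 0.0439 in the simulation, a difference of -0.00132. These values show no agreement beyond that from shared controls. The 3 control libraries were not split, since 1 part would keep a single library.

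KO-Control against WT-Control compares the host genotypes without drug. Neurl1a, a ubiquitin ligase gene on chromosome 19 (47178820 to 47259441, GRCm38), rose by 1.06 (SE 0.15, adjusted p = 0.048), from 6.84 ± 1.31 to 14.2 ± 1.38 CPM (SD, n = 3). It lies within 15 Mb of Adra2a, where genes called between KO and WT tumours clustered, so its rise may not reflect the loss of Adra2a. The clock output genes Tef (0.72, SE 0.12, adjusted p = 0.12) and Dbp (1.49, SE 0.27, adjusted p = 0.18) were among the 5 smallest p, with Mastl (0.38, SE 0.07) and Apol8 (1.01, SE 0.19). G2 and M phase genes had a median of 0.14 with 23 of 24 positive (camera adjusted p = 7.1e-09, adjusted p = 1 with an estimated correlation), Kif23, a kinesin of cell division, being the 1 that passed when adjusted over the list alone (0.23, SE 0.06) with 0 over all genes. The glucocorticoid response list had a median of 0.25, ribosomal protein 0.08 and fibroblast and matrix -0.16, with no member passing (adjusted p = 1 for each with an estimated correlation). Fkbp5, a chaperone induced by glucocorticoids, was at 0.32 (SE 0.21) and Col1a1 at -0.43 (SE 0.17). The T cell list had a median of 0.06 (adjusted p = 0.47).

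edgeR called 1 gene, with 594 at an unadjusted p under 0.05, fewer than the 806 that chance gives, against 17 by DESeq2 and 1 by voom. All 4 list calls had adjusted p = 1 with an estimated correlation, and without 1 library the differences of mean levels of all 4 fell by over 1.5 times, glucocorticoid response from 0.21 to 0.05 without KO-Control 2. The gene count was 0 with a stricter filter, total-count scaling, the replicate number as a block, these groups fitted alone or a term for Y-linked transcripts. It was also 0 without WT-Control 3 or without any 1 of the 3 KO-Control libraries and 2 without WT-Control 1. The list count ranged from 2 without WT-Control 2 to 13 without KO-Control 2, with 9 without WT-Control 1 and 7 without WT-Control 3.

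KO-Clonidine against WT-Clonidine compares treated tumours by host genotype. Ribosomal protein genes were higher in KO-Clonidine in all 25 members (median 0.31, adjusted p = 0.25 with an estimated correlation), and 21 rose over all genes and 24 when adjusted over the list alone, among them Rps6 (0.34, SE 0.06) and Rps2 (0.41, SE 0.08). Gene sets matched to the list in transcript length and level had medians from 0.1 to 0.27. Members of the integrated stress response list that rose were Trib3 by 1.02 (SE 0.18), from 21.8 ± 1.15 to 44.1 ± 6.08 CPM, Asns by 0.59 (SE 0.11), Sesn2 by 0.53 (SE 0.1) and Chac1 by 0.76 (SE 0.18). In this list (median 0.26, adjusted p = 0.39 with an estimated correlation) 6 of 25 passed over all genes and 9 when adjusted over the list alone. T cell genes were lower in all 20 members (median -0.81, adjusted p = 0.39 with an estimated correlation), with Cd5 (-1.36, SE 0.24), Icos (-1.39, SE 0.3) and Cd6 (-1.23, SE 0.28) passing over all genes and 14 when adjusted over the list alone. Among regulatory T cell genes (median -0.7, adjusted p = 0.25 with an estimated correlation) Ikzf4 (-1.15, SE 0.22) and Ikzf2 (-0.61, SE 0.15) passed over all genes and 7 of 10, Foxp3 (-1.11, SE 0.29) included, when adjusted over the list alone. Of the interferon gamma response (median -0.37, adjusted p = 0.45 with an estimated correlation), Iigp1 (-0.8, SE 0.14), Irgm2 (-0.47, SE 0.11), Serpina3g (-0.94, SE 0.22) and Gbp7 (-0.52, SE 0.13) were the 4 that fell over all genes, with 13 lower and 1 higher when adjusted over the list alone.

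Among called genes that met the level and no-overlap terms of the rule for named genes, the largest rises included those in Neurl1a (1.26, SE 0.15, adjusted p = 0.0051), Trib3, Ddit4 (0.94, SE 0.14), Prelid2 (0.93, SE 0.22), the growth factor gene Hbegf (0.89, SE 0.21), Pyroxd2, of chromosome 19 (0.88, SE 0.21) and Tcim (0.82, SE 0.19). The largest falls by the same rule were in Cd300e, an activating receptor of monocytes (-2, SE 0.43), the potassium channel gene Kcnt2 (-1.7, SE 0.37), Klra17, of the Ly49 receptor family (-1.68, SE 0.42), Serpina3f (-1.36, SE 0.32), the cytokine receptor gene Il18r1 (-1.14, SE 0.25), Pira2, a myeloid immunoglobulin-like receptor (-1.14, SE 0.2), Sectm1a (-1.1, SE 0.23) and Lyz1, a lysozyme (-1.04, SE 0.22). Hypoxia genes had a median of 0.58 (adjusted p = 0.43 with an estimated correlation), with Ddit4 passing over all genes and 16 of 22 when adjusted over the list alone. Ddit4 is also a member of the glucocorticoid response list and is the 1 gene that passed there. The 8 erythroid genes had a median of 2.81 (adjusted p = 0.39 with an estimated correlation), with 1 passing over all genes and 6 when adjusted over the list alone. Red cell transcripts varied widely within KO-Clonidine, Hbb-bt, a beta globin, being at 147 ± 123 CPM. In the pericyte list (-0.23, adjusted p = 0.43 with an estimated correlation) Notch3 (-0.56, SE 0.11) and Rgs5 (-0.52, SE 0.11) fell over all genes and 5 of 12 when adjusted over the list alone. Oxidative phosphorylation genes had a median of 0.16 (adjusted p = 0.39 with an estimated correlation), with Ndufa1 (0.25, SE 0.06) and Cox4i1 (0.26, SE 0.06) passing over all genes and 3 when adjusted over the list alone, and sets matched to this list in transcript length and level had medians from 0.08 to 0.2.

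The other called lists had medians of -0.83 (mast cell and eosinophil), -0.68 (skeletal muscle), -0.66 (NK cell), -0.56 (lymphocyte-attracting chemokines, with 1 passing over all genes and 4 when adjusted over the list alone), -0.52 (plasmacytoid dendritic cell), -0.5 (alternative macrophage, with 1 passing over all genes and 2 when adjusted over the list alone), -0.45 (MHC class II), -0.44 (conventional dendritic cell, with 2 passing when adjusted over the list alone and 0 over all genes), -0.33 (checkpoint, with 8 of 15 passing when adjusted over the list alone and 0 over all genes), -0.27 (endothelial), 0.25 (glucocorticoid response, with 1 passing in either way) and 0.13 (G2 and M phase, with 2 passing when adjusted over the list alone and 0 over all genes). edgeR called 403 genes, 293 higher and 110 lower, against 1148 by DESeq2 and 1266 by voom, with 3154 at an unadjusted p under 0.05. With total-count scaling 249 were called, 43 higher and 206 lower, 151 of them shared, so the balance of higher and lower calls depends on scaling. The count rests on single libraries: it was 1 without WT-Clonidine 3, 2 without WT-Clonidine 2, 5 without KO-Clonidine 3, 48 without WT-Clonidine 1 and 70 without KO-Clonidine 1, and 4 when these 2 groups were fitted alone. A term for Y-linked transcripts, which 0 of 3 KO-Clonidine libraries and 2 of 3 WT-Clonidine libraries had, gave 213 calls, 160 shared. Of the 21 called lists 7 were higher and 14 lower. Differences of mean levels fell by over 1.5 times in 4 of them, hypoxia (0.58 to 0.3), skeletal muscle (-0.8 to -0.45) and glucocorticoid response (0.31 to 0.16) without KO-Clonidine 3, and G2 and M phase (0.15 to 0.07) without WT-Clonidine 3. None held with an estimated correlation, where the adjusted p ranged from 0.25 to 0.53, and fry called 6.

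Guanabenz in mice without the receptor was read from the libraries titled KO-Guanabenz, whose treatment entry reads untreated, against KO-Control. Ndufa12, a subunit of complex I, fell by 0.42 (SE 0.06), from 79.3 ± 2.26 to 59.2 ± 4.14 CPM, and Hddc2, a nucleotide phosphohydrolase gene, fell by 0.73 (SE 0.11), both with adjusted p = 0.034. All 25 ribosomal protein genes were lower (median -0.21, adjusted p = 0.79 with an estimated correlation), 21 of them when adjusted over the list alone and 0 over all genes, with Rpl13 at -0.27 (SE 0.06). Sets matched to the list in transcript length and level had medians from -0.21 to -0.06, and the shortest and longest 20% of genes -0.11 and 0.09. Skeletal muscle genes were lower in all 17 members (median -0.89, adjusted p = 0.87 with an estimated correlation), with 11 passing when adjusted over the list alone and 0 over all genes, for example Tnni2, a fast muscle troponin (-0.87, SE 0.25). KO-Guanabenz 1 stood apart, with levels relative to WT-Control of -1.92 for skeletal muscle, -1.7 for adipocyte, -1.46 for mast cell and eosinophil and -2.74 for skin epidermis genes. Without it the differences of mean levels went from -1 to -0.57 (skeletal muscle), -0.8 to -0.35 (adipocyte) and -0.9 to -0.42 (mast cell and eosinophil). MHC class II genes had a median of 0.57 (adjusted p = 0.87 with an estimated correlation), Cd74, the invariant chain, being at 1260 ± 525 against 625 ± 139 CPM. The interferon gamma list had a median of 0.19 (adjusted p = 0.87 with an estimated correlation), with Socs1, a cytokine signalling inhibitor (0.29, SE 0.09), and Batf2 (0.48, SE 0.14) among the 6 of 30 that passed when adjusted over the list alone, with 0 over all genes.

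The T cell list had a median of 0.34 (camera adjusted p = 0.029, adjusted p = 0.87 with an estimated correlation), with Cd8a at 0.86 (SE 0.36) and no member passing. The other 5 of the 10 called lists had medians of 0.27 (fibroblast and matrix), 0.14 (immediate early genes, with Fosb at 0.88, SE 0.26), -0.15 (oxidative phosphorylation, 4 of 22 passing when adjusted over the list alone and 0 over all genes, matched sets from -0.14 to -0.04), -0.58 (adipocyte) and -0.79 (mast cell and eosinophil). Differences of mean levels also fell by over 1.5 times for interferon gamma (0.22 to 0.13) and MHC class II (0.55 to 0.36) without KO-Guanabenz 2 and for immediate early genes (0.19 to 0.1) without KO-Control 3, 6 of the 10 lists in all. Sarnp (-0.48, SE 0.08), Snrpf (-0.39, SE 0.06), a spliceosome protein, and Dnm1 (0.65, SE 0.11) followed at adjusted p = 0.055. edgeR called 2 genes, with 2437 at an unadjusted p under 0.05, against 457 by DESeq2 and 343 by voom. With total-count scaling 15 genes were called, 5 higher and 10 lower, so the count and its balance depend on scaling. The count was 0 with the replicate number as a block or with these groups fitted alone. The ribosomal list had adjusted p = 0.79 and the other 9 adjusted p = 0.87 with an estimated correlation, and fry called 1 list, the ribosomal. The gene count was 0 without KO-Control 2, KO-Control 3, KO-Guanabenz 1 or KO-Guanabenz 2, 11 without KO-Control 1 and 85 without KO-Guanabenz 3. The list count was 16 without KO-Control 2 and 19 without KO-Guanabenz 3.

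The guanabenz effect differed between genotypes for Per2, which rests on the libraries titled KO-Guanabenz and labelled untreated. Per2 (gene 18627, chromosome 1, 91415977 to 91459351, GRCm38) had a difference of 1.93 (SE 0.23, adjusted p = 0.0055), with 1.15 (SE 0.17) in WT and -0.78 (SE 0.17) in KO mice. Other clock genes had the next smallest p: Tef at 1.09 (SE 0.17, adjusted p = 0.08), Dbp at 2.13 (SE 0.39, adjusted p = 0.21) and Per3 at 1.28 (SE 0.23, adjusted p = 0.21), followed by Sh3gl3 (-1.03, SE 0.22). In the fibroblast and matrix list (median -0.37, adjusted p = 0.89 with an estimated correlation), Col1a1 (-0.78, SE 0.24), Col3a1 (-0.66, SE 0.2), Col1a2 and Sparc, all collagen or matrix genes, passed when adjusted over the list alone with 0 over all genes. Of the glucocorticoid response (0.34, adjusted p = 0.89 with an estimated correlation), Tsc22d3 (0.51, SE 0.15) and Zbtb16 (2.59, SE 0.82) passed in the same way with 0 over all genes. Of G2 and M phase genes (0.16, adjusted p = 0.89 with an estimated correlation) Kif23 (0.33, SE 0.09) did so, again with 0 over all genes.

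The other called lists were mast cell and eosinophil (1.2), skeletal muscle (0.63), alternative macrophage (0.43), adipocyte (0.26), S phase (0.17), MHC class II (-0.46), type I interferon (-0.17), integrated stress response (-0.13) and interferon gamma (-0.1, turning direction without WT-Guanabenz 1, adjusted p = 0.59), with no member passing. The ribosomal list had a median of 0.01 (adjusted p = 0.37) and the T cell list one of -0.14 (adjusted p = 0.14). edgeR called 1 gene, with 920 at an unadjusted p under 0.05, against 13 by DESeq2 and 2 by voom. Each of the 12 list calls had adjusted p = 0.89 with an estimated correlation. Differences of mean levels fell by over 1.5 times without 1 library in 10 of the 12, all but alternative macrophage and fibroblast and matrix. Without KO-Guanabenz 1, with its treatment label in conflict, they went from 1.15 to 0.68 (mast cell and eosinophil), 0.75 to 0.32 (skeletal muscle) and 0.77 to 0.32 (adipocyte), and for MHC class II from -0.4 to -0.13 without WT-Guanabenz 1. The gene count rose to 4 without WT-Guanabenz 1 and 2 without WT-Control 2, WT-Guanabenz 3 or KO-Control 2. The list count to 19 without WT-Guanabenz 2 and 21 without WT-Guanabenz 3.

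**Figure D3:**
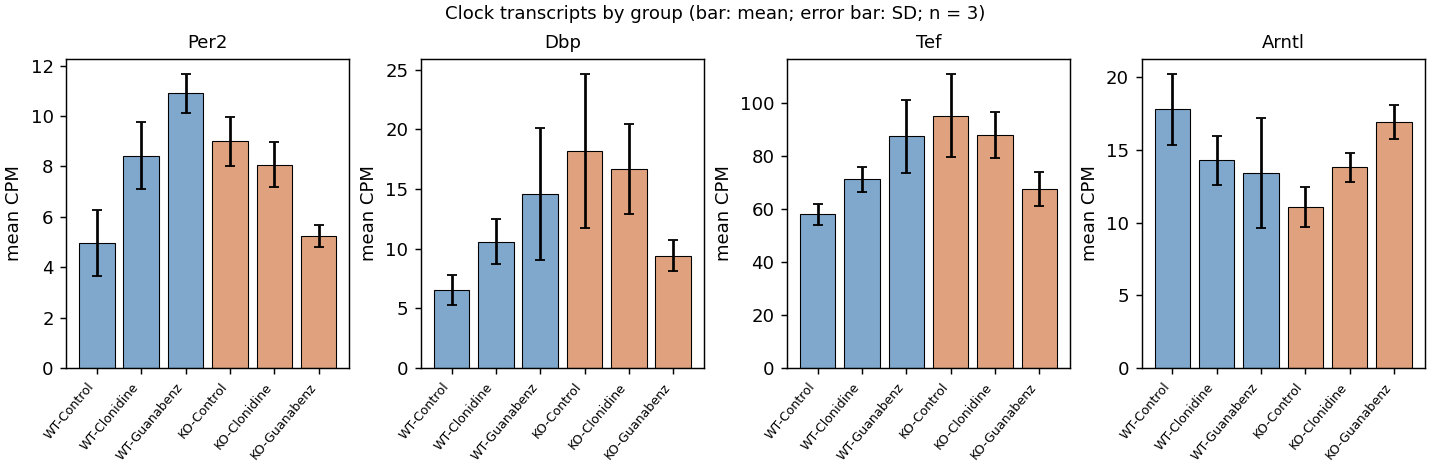
Mean CPM of 4 circadian clock genes in each group (bars; error bars SD, n = 3; WT blue, KO orange; KO-Guanabenz by title, its treatment entry being untreated). Per2 is at 4.96 CPM in WT-Control and 10.9 in WT-Guanabenz, and at 8.99 in KO-Control and 5.24 in KO-Guanabenz; Arntl, of the opposite arm of the clock, is at 17.8, 13.4, 11.1 and 16.9 in the same order.

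Averaged over the 3 treatments, a comparison chosen after the data were seen, KO and WT tumours differed in several genes of chromosome 19. Neurl1a rose by 1.24 (SE 0.09, adjusted p = 2.6e-06), from 6.76 ± 0.887 to 16 ± 2.3 CPM (SD, n = 9), and Pyroxd2 by 0.8 (SE 0.12). Scd3, a fatty acid desaturase, fell by 1.07 (SE 0.12), Mfsd13a fell by 0.85 (SE 0.1), and the scarce transcripts of Sorcs1, Rbm20 and Tlx1 fell by 2.02, 1.25 and 3.35, Tlx1 from 0.0913 ± 0.0376 CPM. Other genes that rose include Asns (0.32, SE 0.06), Sesn2 (0.29, SE 0.06), the tRNA synthetase genes Sars (0.23, SE 0.04) and Nars (0.18, SE 0.03), the glycine transporter gene Slc6a9 (0.38, SE 0.06) and Eif4ebp1 (0.3, SE 0.05), a translation repressor. The genes of this paragraph were chosen after their values were seen.

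Ribosomal protein genes were higher in KO tumours in all 25 members (median 0.14, adjusted p = 0.63 with an estimated correlation), with 3 rising over all genes and 22 when adjusted over the list alone. The regulatory T cell list had a median of -0.34 (adjusted p = 0.65 with an estimated correlation), with 7 of 10 passing when adjusted over the list alone and 0 over all genes. Its mean level relative to WT-Control was -0.33 in KO-Clonidine against 0.43 in WT-Clonidine. It was -0.03 in KO-Control, and -0.15 in KO-Guanabenz against -0.16 in WT-Guanabenz, so the average came from clonidine. In the same order, ribosomal levels were 0.11 against -0.19, 0.07, and -0.15 against -0.19. Erythroid levels were 1.33 against -0.95, 0.04, and -0.52 against -0.23. Other called lists with higher medians were erythroid (0.9), hypoxia (0.25), integrated stress response (0.12, 2 passing over all genes, and 5 higher and 1 lower when adjusted over the list alone), immediate early genes (0.12), G2 and M phase (0.09), MHC class I (0.09) and oxidative phosphorylation (0.07). Those with lower medians were skeletal muscle (-0.45), alternative macrophage (-0.41), skin epidermis (-0.33), mast cell and eosinophil (-0.32), adipocyte (-0.25), lymphocyte-attracting chemokines (-0.25), conventional dendritic cell (-0.2), interferon gamma (-0.12) and pericyte and smooth muscle (-0.08). In edgeR 67 genes were called, 46 higher and 21 lower, with 2810 at an unadjusted p under 0.05, against 618 by DESeq2 and 362 by voom. With total-count scaling there were 38, 9 higher and 29 lower, so the balance of higher and lower calls depends on scaling. Counts without 1 library ranged from 7 (KO-Guanabenz 1, whose treatment label is in conflict) to 111 (WT-Guanabenz 3). Differences of mean levels fell by over 1.5 times without 1 library in 6 of the 18 lists. These were mast cell and eosinophil (-0.39 to -0.23), adipocyte (-0.37 to -0.21) and skin epidermis (-0.73 to -0.42) without KO-Guanabenz 1. The others were erythroid (0.68 to 0.45) without KO-Guanabenz 3, hypoxia (0.24 to 0.14) without KO-Clonidine 3 and MHC class I (0.09 to 0.05) without WT-Guanabenz 1. None of the 18 list calls held with an estimated correlation, where the adjusted p ranged from 0.63 to 0.69, and fry called 1.

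**Figure D4:**
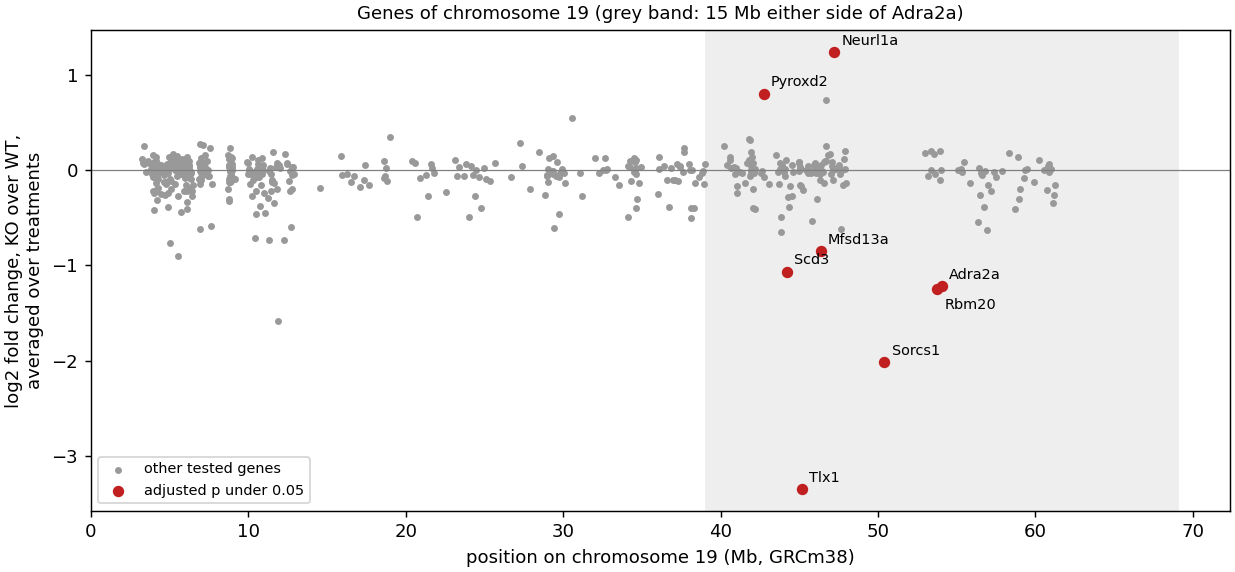
Log2 fold change of KO over WT, averaged over treatments, for the tested genes of chromosome 19 by position in Mb (GRCm38), with genes at adjusted p under 0.05 in red and a grey band 15 Mb either side of Adra2a. Outside Adra2a itself, 7 of the 161 genes tested in the band were called, 2 higher and 5 lower.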

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

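The tests in this part were chosen after the results were seen. Only the predictions for the split tests of the T cell and ribosomal lists were written beforehand. The plan fixed before the data were examined held no split test and did not single out these lists. A difference between the WT and KO responses, by the test of that difference itself, brought each result below to attention, except the genes near Adra2a, which stood out in KO against WT tumours.

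T cell and ribosomal genes with clonidine: the WT response exceeded the KO response by a median of 0.79 for the T cell list and lay below it by -0.23 for the ribosomal list. Fewer tumour cells in the samples would raise every host cell type alike, and the upper quartile of macrophage and monocyte genes in WT mice was 0.12, below the lower quartile of 0.54 of the T cell list, so that explanation is set aside as the whole cause. For the change within WT mice, unequal numbers of libraries with Y-linked transcripts and the depth of WT-Control 3 are set aside too (T cell median 0.82 among libraries with those transcripts and 0.78 without WT-Control 3, ribosomal median -0.16 among those libraries). For the difference between genotypes the Y-linked imbalance can give at most 0.15 of the T cell and -0.03 of the ribosomal value (95% limits). That bound takes the effect of Y-linked status to be the same in every group, and only on that term is the imbalance set aside as the whole cause. Y-linked transcripts were present in 0 of 3 KO-Clonidine and 3 of 3 WT-Control libraries. A clonidine response that varies with Y-linked status therefore cannot be told from the genotype difference. For the ribosomal list in WT mice a trend with transcript length stays open, because gene sets of matched length and level had medians from -0.17 to -0.06 against -0.18 for the list. A response through the receptor could account for the T cell difference. Of 100 splits of the libraries 2, counting the real one, gave as small a camera p for it (8.2e-12 against 1.5e-12 in the other). For the ribosomal list 5 did (7.7e-17 against 1.4e-19). These splits exchanged clonidine and control libraries within each genotype, so they ask whether clonidine had any effect. They cannot tell equal from unequal effects in WT and KO mice. On the question they ask, chance can be excluded at 0.05 for the T cell list, but only when it is taken alone. That makes no allowance for the other lists tested. For the ribosomal list chance cannot be excluded. Both calls are lost (adjusted p = 0.36 with an estimated correlation).

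Genes near Adra2a: 7 of 161 genes tested within 15 Mb of Adra2a were called between KO and WT tumours, or 4.35%, against 59 of 15963 elsewhere, or 0.37% (Fisher's exact p = 4.1e-06, odds ratio 12.2, 95% interval 4.64 to 27.4). DNA of another strain carried along with the disrupted gene predicts such a cluster, and the called genes spanned 42725857 to 53867083 on chromosome 19 (GRCm38). Effects downstream of the receptor alone predict no cluster, so the lower limit of 4.64 argues against them as the whole cause. The window was drawn after the cluster was seen in these same calls, and neither the p nor the interval allows for that choice. Of the 7 genes, Tlx1, Sorcs1 and Rbm20 were scarce, at 0.0913, 0.14 and 0.251 CPM in WT tumours. Reads of a diverged haplotype that fail to match the reference would lower a gene in the genotype that carries it. With KO hosts carrying it, that could account for the 5 of the 7 genes lower in KO but not for the 2 that were higher (Neurl1a and Pyroxd2). Which genotype would carry it is not known, and no value here decides that. The labels give no strain for the hosts, so differences in these 7 genes may not reflect the loss of Adra2a.

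Clock genes: the response of Per2 to guanabenz differed between genotypes by 1.93, with the libraries titled KO-Guanabenz, and labelled untreated, on the KO side. Arntl, of the opposite arm of the clock, had a difference of -1.01 (SE 0.22, adjusted p = 0.53 in edgeR), the direction that a different time of day at collection predicts, while Clock of that arm was at -0.06 (SE 0.13) and Npas2 at -0.13 with an SE of 0.7, too wide to tell. Similar directions were seen without guanabenz, in the clonidine difference (Per2 0.93, Arntl -0.63) and between the controls (Dbp 1.49, Arntl -0.68), and none of these 4 passed. These comparisons share their control libraries with the guanabenz difference, so they are not separate sightings. Between KO-Clonidine and WT-Clonidine, with no control library, Per2 was at -0.06 (SE 0.16) and Arntl at -0.05 (SE 0.16). Nr1d1 was the only clock gene examined that was called between KO and WT over the treatments (0.56, SE 0.11, adjusted p = 0.039 in edgeR). The change of Per2 with guanabenz in KO mice (-0.78, SE 0.17) and KO-Guanabenz minus WT-Guanabenz (-1.06, SE 0.17) are parts of the difference by which Per2 was chosen, so they test no shift by guanabenz or by loss of Adra2a. The labels give no time of collection, so a response to guanabenz that needs the receptor cannot be told from collection at another hour.

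For clonidine, the other lists with a different response in WT than in KO mice had median differences of 1.26 (mast cell and eosinophil), 0.64 (regulatory T cell), 0.59 (alternative macrophage), 0.58 (NK cell), 0.51 (lymphocyte-attracting chemokines and receptors), 0.48 (T cell checkpoint and exhaustion), 0.47 (skeletal muscle), 0.31 (conventional dendritic cell), 0.3 (interferon gamma response), 0.26 (endothelial cell), -0.13 (oxidative phosphorylation), -0.23 (fibroblast and matrix), -0.3 (integrated stress response and unfolded proteins), -0.58 (hypoxia and glycolysis) and -2.65 (erythroid cell). For guanabenz, with the treatment of KO-Guanabenz in conflict between labels, they had 1.2 (mast cell and eosinophil), 0.63 (skeletal muscle), 0.43 (alternative macrophage), 0.34 (glucocorticoid response), 0.26 (adipocyte), 0.17 (S phase), 0.16 (G2 and M phase), -0.1 (interferon gamma response), -0.13 (integrated stress response and unfolded proteins), -0.17 (type I interferon response), -0.37 (fibroblast and matrix) and -0.46 (MHC class II presentation). All of these calls were lost, with adjusted p from 0.36 to 0.6 for clonidine and adjusted p = 0.89 for guanabenz with an estimated correlation.

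Libraries were also regrouped in every way, or in 100 drawn ways for the comparisons of 4 or 6 groups, and called again, counting the real grouping. Comparisons of 3 against 3 have 10 splits, too few to exclude chance. Their real counts of called genes and highest other counts were 0 and 0 for WT-Clonidine against WT-Control (reached in 10 of 10), 3 and 3 for KO-Clonidine against KO-Control (2 of 10), 0 and 0 for WT-Guanabenz against WT-Control (10 of 10), 0 and 0 for WT-Clonidine against WT-Guanabenz (10 of 10), 1 and 8 for KO-Control against WT-Control (2 of 10), 403 and 0 for KO-Clonidine against WT-Clonidine (1 of 10) and 2 and 1 for KO-Guanabenz against KO-Control (1 of 10). For called lists they were, in the same order, 16 and 16 (4 of 10), 5 and 19 (8 of 10), 5 and 23 (10 of 10), 22 and 23 (3 of 10), 4 and 17 (10 of 10), 21 and 22 (3 of 10) and 10 and 19 (9 of 10). Some splits called several times as many lists as the real grouping; whether structure among the libraries or correlation between the genes of a list brings this about was not tested, and the number of called lists carries little weight.

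For the difference of the clonidine effect, real and highest other counts were 0 and 12 genes (100 of 100) and 17 and 24 lists (17 of 100), so chance cannot be excluded for either count. For that of the guanabenz effect they were 1 and 8 genes (7 of 100) and 12 and 24 lists (61 of 100), and chance cannot be excluded either. For KO against WT over the treatments they were 67 and 39 genes (1 of 100) and 18 and 27 lists (25 of 100). For the gene count chance can be excluded at 0.05 only within these 100 splits. That makes no allowance for the choice of this comparison after the data were seen, and a split outside the 100, given next, called more genes. For the list count chance cannot be excluded. A second set of 60 drawn splits, made while the scripts were being written, held 1 that called 331 genes for the guanabenz difference, in which WT-Control and WT-Guanabenz were exchanged whole, which makes it the guanabenz effect averaged over both genotypes, and 1 that called 173 for KO against WT, in which 2 libraries changed place.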

How the results depend on the processing

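Of the settings below, the Y-linked term, the length correction and all settings of KO against WT over treatments were chosen after the results were seen. Where a setting ended or moved a count, the cause was not tested. Numbers are called genes unless lists are named, comparisons being named by first group, and KO-Guanabenz is taken by title against its treatment entry. edgeR, DESeq2 and voom called 0, 355 and 773 in WT clonidine, 3, 29 and 3 in KO clonidine, 0, 37 and 2 in the clonidine difference, 0, 171 and 6 in WT guanabenz, 0, 4 and 1 in clonidine against guanabenz, 1, 17 and 1 in KO against WT controls, 403, 1148 and 1266 in KO against WT clonidine, 2, 457 and 343 in KO guanabenz, 1, 13 and 2 in the guanabenz difference and 67, 618 and 362 in KO against WT over treatments. Called lists numbered 16, 5, 17, 5, 22, 4, 21, 10, 12 and 18 in the same order.

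Without a low-count filter the clonidine difference had 3 and WT guanabenz 1, and with a stricter filter KO against WT controls had 0 and KO guanabenz 19. With RLE WT guanabenz had 1. With total-count scaling WT guanabenz had 1, KO against WT controls 0, KO against WT clonidine 249, KO guanabenz 15, the guanabenz difference 2 and KO against WT over treatments 38. The compared groups fitted alone gave 0 in KO clonidine, in KO against WT controls and in KO guanabenz and 4 in KO against WT clonidine. KO-Guanabenz read as KO-Control gave 0 in KO clonidine and 2 in KO against WT controls, and KO against WT clonidine without the KO-Guanabenz libraries had 220. The Y-linked term gave 1 in KO clonidine, 2 in the clonidine difference, 0 in KO against WT controls, 213 in KO against WT clonidine and 11 in KO guanabenz. The length correction gave 3 lists in WT guanabenz and 17 in KO guanabenz. An estimated correlation gave 0 lists in every comparison, and fry 6 in KO against WT clonidine, 1 in KO guanabenz, 1 in KO against WT over treatments and 0 in the others. Total-count scaling moved the median over all genes by at most 0.09.

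The replicate block gave 0 in KO clonidine, in KO against WT controls and in KO guanabenz, 333 in KO against WT clonidine and 60 in KO against WT over treatments, with 23 lists in clonidine against guanabenz, 19 in the clonidine difference and 13 in the guanabenz difference. Replicate numbers did not pair the libraries: the mean correlation of deviations from group means was -0.004 over 45 pairs with the same number (10 above 0.1) and 0.002 over 90 other pairs (19 above 0.1).

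Without 1 library at a time, counts ranged from 0 to 55 in WT clonidine (55 without WT-Control 2), 0 to 3 in KO clonidine, 0 to 2 in the clonidine difference (1 without WT-Clonidine 1, 2 without KO-Clonidine 2), 0 to 1 in WT guanabenz and in clonidine against guanabenz, 0 to 2 in KO against WT controls, 1 to 312 in KO against WT clonidine, 0 to 85 in KO guanabenz, 1 to 4 in the guanabenz difference and 7 to 111 in KO against WT over treatments. There the count moved by over 1.5 times without WT-Clonidine 1, 2 or 3, WT-Control 2, WT-Guanabenz 2 or 3, KO-Clonidine 1 or 3, KO-Control 1 or 2, or KO-Guanabenz 1 or 2. Lists ranged in the same order over 14 to 21, 2 to 12 (12 without KO-Clonidine 2 or KO-Control 2, 2 without KO-Clonidine 3), 15 to 21, 3 to 14, 17 to 24, 2 to 13, 19 to 25, 7 to 19, 8 to 21 and 10 to 25 (10 without WT-Guanabenz 3, 11 without KO-Clonidine 3). The correlation of the clonidine and guanabenz effects was 0.55 to 0.64 without 1 control.

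Some lists turned direction without 1 library, and their camera adjusted p ranged as follows without 1 library at a time. G2 and M phase turned without WT-Clonidine 3 in WT clonidine (0.026 to 0.91) and in the clonidine difference (0.043 to 0.99). Hypoxia in KO clonidine turned between omissions (0.041 without KO-Clonidine 1, 0.0096 without KO-Control 2, range 0.00014 to 0.55). In WT clonidine vs WT guanabenz NK cell (0.52, range 1.7e-05 to 0.52), interferon gamma (0.3, range 3e-06 to 0.3) and MHC class I (0.00063, range 0.00063 to 0.27) turned without WT-Guanabenz 1, and the list NF-kB and TNF response, WT clonidine vs WT guanabenz, without WT-Guanabenz replicate 3 (0.36, range from 3.9e-05 without WT-Guanabenz replicate 1). In KO against WT controls type I interferon turned without WT-Control 3 (0.0095) or KO-Control 2 (0.012), up to 0.75, and hypoxia without KO-Control 2 (0.02), up to 0.85. In the guanabenz difference interferon gamma turned without WT-Guanabenz 1 (0.59, range 0.00042 to 0.59). Totals of 54.7 (in units of 1e6) or more leave counting error small for all but scarce genes such as Adra2a.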

Other observations

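The tests in this part were chosen after the results were seen.

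The effect of guanabenz averaged over both genotypes, with KO-Guanabenz taken by title against its treatment entry, was a setting added because a regrouping of the libraries, the same contrast under another name, called 331 genes. Its calls restate that regrouping and are no independent test of it. Ribosomal protein genes had a median of -0.2 (camera adjusted p = 1.3e-20, adjusted p = 0.41 with an estimated correlation) and oxidative phosphorylation genes -0.14 (adjusted p = 1.8e-08, adjusted p = 0.56 with an estimated correlation). Gene sets matched to the ribosomal list in transcript length and level had medians from -0.19 to -0.08 with guanabenz in WT mice and from -0.21 to -0.06 in KO mice, against list medians of -0.18 and -0.21, so a trend with length stays open as the cause. Rps14 fell by 0.37, Cd63, a tetraspanin of lysosomes and secreted vesicles, fell by 0.41 (adjusted p = 0.018), Mif, a cytokine gene, fell by 0.37 (adjusted p = 0.028) and Hddc2 fell by 0.47 (adjusted p = 0.018). Ipcef1, of an ARF6 exchange factor complex, rose by 0.75 (SE 0.12, adjusted p = 0.018), and Fcgr4, an activating Fc receptor of myeloid cells, rose by 0.55 (adjusted p = 0.034). Skeletal muscle genes had a median of -0.6, MHC class II genes 0.32 and interferon gamma response genes 0.18. edgeR called those 331 genes, 78 higher and 253 lower, with 3198 at an unadjusted p under 0.05; the count was 0 without WT-Control 1 and 1073 without WT-Guanabenz 3. With an estimated correlation 0 of the 5 lists held.

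Aminoacyl-tRNA synthetases load amino acids onto tRNA, and Nars and Sars rose in KO tumours over all treatments together with Asns and Sesn2. The hypothesis that the cytosolic synthetases are higher as a group was tested on the 18 others. Their median was 0.14 with 17 of 18 above 0 (camera in limma, p = 1.1e-08, p = 0.057 with an estimated correlation). The camera p-values of this 1 list are unadjusted, with no allowance for the several comparisons in which it was tested. The list was prompted by Nars and Sars in these same libraries. Of the 18 genes 12 passed when adjusted over the list alone and 0 over all genes. Between KO-Clonidine and WT-Clonidine the median was 0.24, with 6 passing over all genes and 12 when adjusted over the list alone (unadjusted camera p = 0.045 with an estimated correlation). Between KO-Control and WT-Control it was 0.05 with 0 passing (unadjusted camera p = 0.34 with an estimated correlation). With clonidine in WT mice it was -0.12, with 2 of 18 above 0. Between KO-Guanabenz, with its treatment entry in conflict, and WT-Guanabenz it was 0.08 with 0 passing (unadjusted camera p = 0.35 with an estimated correlation). The clonidine effect differed between genotypes by a median of -0.17 (unadjusted camera p = 0.12 with an estimated correlation). A larger difference under clonidine is therefore not established, and these values do not establish higher synthetase levels in KO tumours as such.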
